A study of Mus musculus with 7 samples.

How the data were processed

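B cells were isolated on magnetic columns from the spleens of 3 Batf knockout (KO) and 4 wild-type mice on a C57BL/6J background, per the labels. They were cultured for 6 h with lipopolysaccharide (LPS, 20 µg/mL), the bacterial ligand of TLR4, and interleukin-4 (IL-4, 20 ng/mL), and total RNA was sequenced as paired-end libraries on an Illumina HiSeq, per the labels' protocols. Groups were taken from the genotype label. The mouse numbers in the titles differ between the groups, so no sample was paired with another. The design text also states that samples have 2 replicates. What these are is not given in the sources used here, and each of the 7 libraries was treated as 1 mouse.

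The submitters' processing notes name TopHat2 2.0.6, HTSeq 0.5.3p7, edgeR 3.03 and the genome build mm10, without their roles. The gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. One deposited table of the whole series was used. Per the file headers, it gives for each gene the read count in each library and the CPM (counts scaled to a common library total) that the authors computed from them. It also holds the authors' own comparison of the genotypes, as a log2 fold change, a log2 mean CPM, a likelihood ratio (a score with no fixed range), a p-value and a false discovery rate (FDR), per the file headers. The table holds 752 genes, and the highest FDR among them is 0.0499. The ratio of FDR to p-value shows that the authors adjusted over 19734 genes and that the table holds each gene that passed an FDR of 0.05. The table was therefore selected on the contrast it describes. Genes outside it have no value here, and their not being listed says only that they did not pass the authors' threshold.

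The effective library size of each library was recovered as count divided by CPM. It ran from 23675459 to 30844920 reads in the Batf KO libraries and from 24891094 to 44728937 reads in the wild-type libraries. The 752 genes took 5.81% to 6.00% of these reads in Batf KO and 5.53% to 5.57% in wild type. Libraries of 1 group were compared pairwise by a chi-square test of their counts. The statistic per degree of freedom was 17.3 or more in each pair, so no library was treated as a second copy of another. In wild type it was 18.8 for replicates 1 and 2 and 21.2 for replicates 3 and 4. The remaining wild-type pairs gave 34.3 to 50.5, so these libraries were alike in pairs. The cause was not tested, and no result was adjusted for it.

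The test planned for CPM was limma on a log scale. The table also held whole counts, so the counts were tested instead with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with the deposited effective library sizes. Genes with a mean CPM of at least 1 over all samples were fitted (667 genes), and 85 genes fell below this filter. Adjusted p-values are Benjamini-Hochberg values from this test over the 667 fitted genes. Because the genes had been selected on the same contrast, these values check the list and are not independent evidence. A stricter value was computed by adjusting over all 19734 genes the authors tested, with genes outside the table counted as p = 1. This adjustment was chosen after seeing the data. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. The edgeR p-values measure the spread between these mice. For genes with few reads, the ratio of the groups' reads per library size is given with an exact 95% counting interval. Such intervals cover counting error only.

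The edgeR step was tested on simulated counts for the 667 genes, with 200 of them changed. At a log2 fold change of 1 it recovered 100% of the raised genes and 94% of the lowered genes, and at 0.5 it recovered 68% of each. It called 1.93% of the unchanged genes. The simulation gave each gene the same dispersion (spread beyond counting error) of 0.02 and selected no genes. These rates therefore do not carry over to selected genes or to genes that vary more between mice. For Batf and the 3 genes of the series title, an exact two-sided permutation test of the CPM values over the 35 splits of the libraries was run with scipy 1.17.1. The smallest p it allows is 0.0286.

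Gene positions were taken by Ensembl identifier from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, in 1-based coordinates. It held 742 of the 752 identifiers, and 10 were not matched.

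A total of 23 gene lists were fixed before the data were examined. The result of 1 list is not reported here. The others cover immunoglobulin constant genes, AP-1, CNC and IRF partner factors, IL-4 and STAT6 response, NF-kappaB and TLR4 early response, type I interferon response, Wnt pathway, plasma cell programme, B cell identity and germinal centre, marginal zone and B1 B cell markers, MYC and ribosome biogenesis, glycolysis and hypoxia, cell cycle, apoptosis, cytokines and chemokines, circadian and PAR bZIP genes, neighbours of Batf on chromosome 12, sex-linked genes, heat shock and handling stress, and markers of T and NK, myeloid, erythroid and platelet, and stromal cells. The planned set test compares a list with unselected genes and was not used on a selected table. As planned for that case, the numbers of higher and lower members of a list were compared with those of the other fitted genes by Fisher's exact test (two-sided), for the 9 lists with at least 5 fitted members, with Benjamini-Hochberg adjustment over the 9 lists. Fisher's test counts genes as independent units, so its p does not measure the spread between mice. The genes named are Batf and the title genes, the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest adjusted p. Predicted models and pseudogenes were counted and not named. This rule was also fixed before the data were examined, and genes named outside it were chosen after their values were seen.

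The alternatives were another filter or none, scaling by TMM over the listed genes, limma 3.58.1 with pseudocounts of 0.1, 0.5 and 2 CPM, without a trend or with array weights, DESeq2 1.42.0, a 2-fold minimum, the authors' own FDR, the adjustment over 19734 genes with and without the filter, and each library left out in turn.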

Results

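RNA was sequenced from splenic B cells of 3 Batf KO and 4 wild-type mice after 6 h of culture with LPS and IL-4, a combination that induces class switching to IgG1 and IgE. BATF is a basic leucine zipper transcription factor of the AP-1 family that binds DNA together with JUN proteins and with IRF4 or IRF8. The series title puts Nfil3, Wnt10a and Mir155hg under the control of BATF in class switch recombination. The comparison of the genotypes therefore asks which transcripts differ early after activation when Batf is disrupted. Effective library sizes were 23675459 to 30844920 reads in Batf KO and 24891094 to 44728937 reads in wild type.

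Batf itself (ENSMUSG00000034266, chromosome 12, 85686669 to 85709087, plus strand, GRCm38) was measured at 319 ± 11.2 CPM (SD, n = 4) in wild type and 66.5 ± 3.49 CPM (SD, n = 3) in Batf KO. It fell by 2.26 on the log2 scale (SE 0.07), and the Batf KO level was 20.8% of wild type. The adjusted p was 1.01e-07 in edgeR's quasi-likelihood test, and the exact permutation p was 0.0286, the smallest the 35 splits can give. Each Batf KO library lay below each wild-type library. Counts per gene do not show which exons the remaining reads came from.

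Of the title genes, Nfil3, a basic leucine zipper repressor, fell from 250 ± 4.74 CPM (SD, n = 4) to 75.6 ± 2.83 CPM (SD, n = 3) in Batf KO, a 3.31-fold decrease (chromosome 13, 52967209 to 52981073). Wnt10a, a secreted Wnt ligand, was higher in Batf KO, at 14.6 ± 1.19 CPM (SD, n = 3) against 5.18 ± 0.42 CPM (SD, n = 4) in wild type, a 2.83-fold increase (chromosome 1, 74791516 to 74804179). Mir155hg, the host transcript of miR-155, was lower at 379 ± 8.33 CPM (SD, n = 3) against 520 ± 65.5 CPM (SD, n = 4), a 1.37-fold decrease (chromosome 16, 84703167 to 84715245). The edgeR adjusted p was 1.83e-07 for Nfil3, 2.24e-05 for Wnt10a and 0.00223 for Mir155hg. The exact permutation p was 0.0286 for Nfil3 and Wnt10a and 0.0571 for Mir155hg. Adjusted over all 19734 genes, the edgeR p of Mir155hg was 0.0660 and did not pass, while its FDR in the authors' deposited table is 0.0124. The title is the claim of the study to which these samples belong, so the direction of these genes is not independent evidence.

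**Figure D1:**
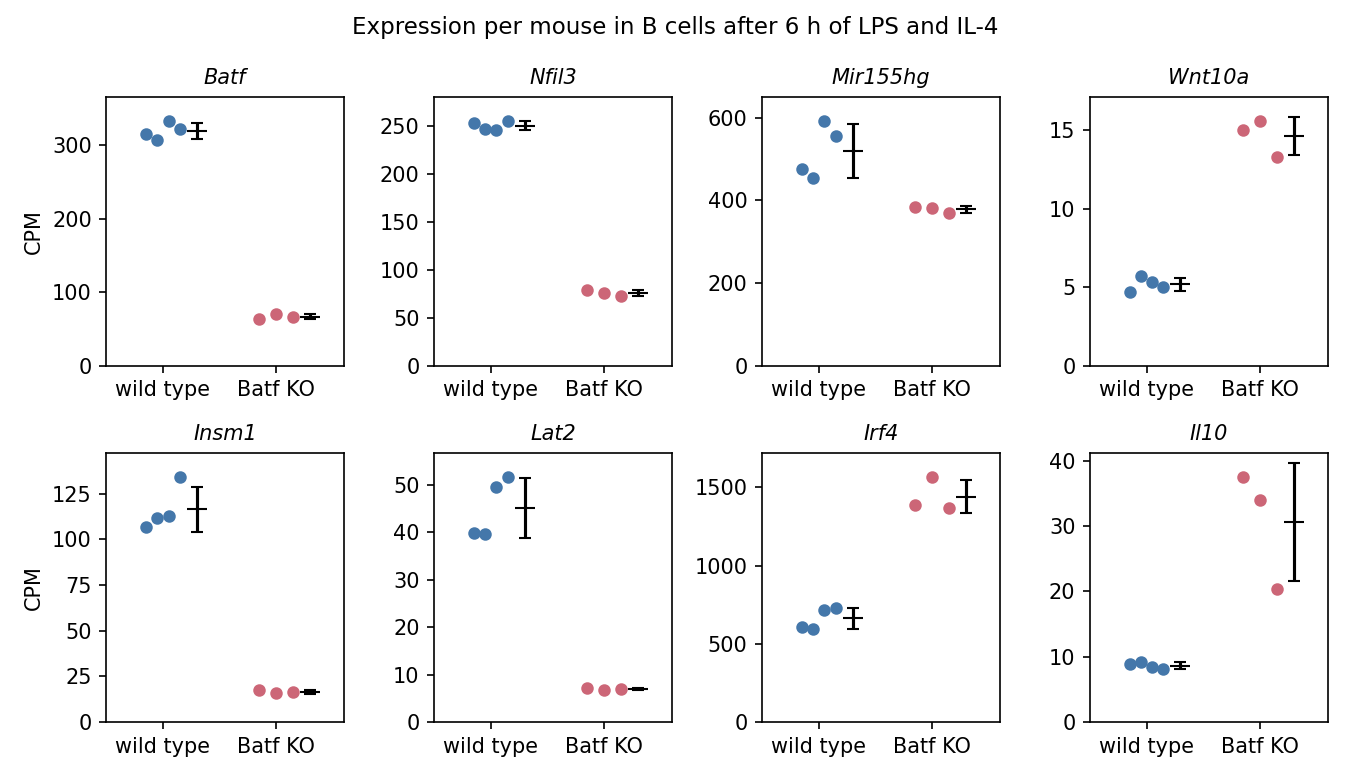
CPM of 8 genes in B cells after 6 h of LPS and IL-4, with 1 point per mouse (4 wild type, 3 Batf KO), and the mean ± SD beside the points. Batf, Nfil3, Insm1 and Lat2 lie lower in each Batf KO mouse, Mir155hg is lower by a smaller margin, and Wnt10a, Irf4 and Il10 lie higher.

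The authors' deposited table lists 384 genes as higher and 368 as lower in Batf KO, of which 104 and 113 differ by at least 2-fold. Of the 667 genes fitted here, 339 were higher and 328 lower, and each passed the threshold, with a highest adjusted p of 0.0347 in edgeR's quasi-likelihood test. The groups did not overlap for 641 of them (317 higher, 324 lower). Chance gives 5.71% for unselected genes, but these genes were selected for a difference between the same libraries, so the number carries no evidence of its own. Because the table holds only genes that had passed the authors' test on the same libraries, the stricter adjustment over 19734 genes is the more cautious count. It left 134 higher and 152 lower.

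Of the named genes past the CPM filter, Tbx21 and Adgrl2 were among those that fell furthest after the immunoglobulin genes. Genes below the filter were not ranked, and some of them fell further. Tbx21, which encodes the transcription factor T-bet, fell from 4.35 ± 3.95 CPM (SD, n = 4) to 0.37 ± 0.16 CPM (SD, n = 3). The adhesion receptor gene Adgrl2 fell 8.18-fold. Insm1, a zinc finger transcription factor gene, fell from 116 ± 12.1 CPM (SD, n = 4) to 16.5 ± 1.01 CPM (SD, n = 3). Lat2, which encodes a membrane adaptor of antigen receptor signalling, fell from 45.2 ± 6.37 CPM (SD, n = 4) to 6.91 ± 0.24 CPM (SD, n = 3). The IL-12 receptor gene Il12rb1, the phosphoinositide 3-kinase gene Pik3cg and the kinase gene Lrrk2 fell 5.84-fold, 4.91-fold and 4.48-fold. Among the named genes that passed the CPM filter, the increases other than that of the ribosomal RNA gene n-R5s64 beside Batf were smaller. Il10, which encodes an anti-inflammatory cytokine, rose from 8.64 ± 0.50 CPM (SD, n = 4) to 30.6 ± 9.08 CPM (SD, n = 3). Grip2, Htra4, Cd8b1, the receptor kinase gene Tyro3, the transporter gene Flvcr2, the interferon-induced genes Ifit3b and Ifit3, the receptor kinase gene Met and Shisa8 rose by between 2.80-fold (Shisa8) and 3.26-fold (Grip2). Tbx21, Il12rb1, Ifit3b and Ifit3 did not pass the edgeR adjustment over 19734 genes, with adjusted p of 0.0880, 0.0706, 0.0557 and 0.0804.

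Immunoglobulin constant genes were lower in Batf KO without exception among those listed: 7 of the 13 annotated members were in the table, and all 7 were lower. Ighm, the constant gene of IgM, fell from 1634 ± 178 CPM (SD, n = 4) to 1202 ± 76.6 CPM (SD, n = 3). Ighg1 fell 2.09-fold, and Ighg3 fell 6.49-fold. Other isotypes were carried by few reads in Batf KO. Igha had 418 reads in the 4 wild-type libraries and 2 in the 3 Batf KO libraries, a 122-fold difference with a counting interval of 33.6 to 1011. Ighg2c had 312 against 2 reads (91.0-fold, 25.0 to 755), Ighg2b 689 against 9 reads (44.7-fold, 23.4 to 98.1) and Ighe 137 against 21 reads (3.81-fold, 2.39 to 6.35). These genes are close copies of one another, and how the counting treated reads shared between them is not given in the sources used here. Among fitted genes 6 of 6 members were lower (Fisher's exact test, which counts genes as independent, adjusted p = 0.0457). All 6 passed adjusted over the list alone and 5 of 6 adjusted over 19734 genes, the exception being Ighm (edgeR adjusted p = 0.0634). With genes called by the adjustment over 19734 genes, the list itself did not pass Fisher's exact test. Its adjusted Fisher p was 0.0687 without Batf KO replicate 2 and also without replicate 3.

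**Figure D2:**
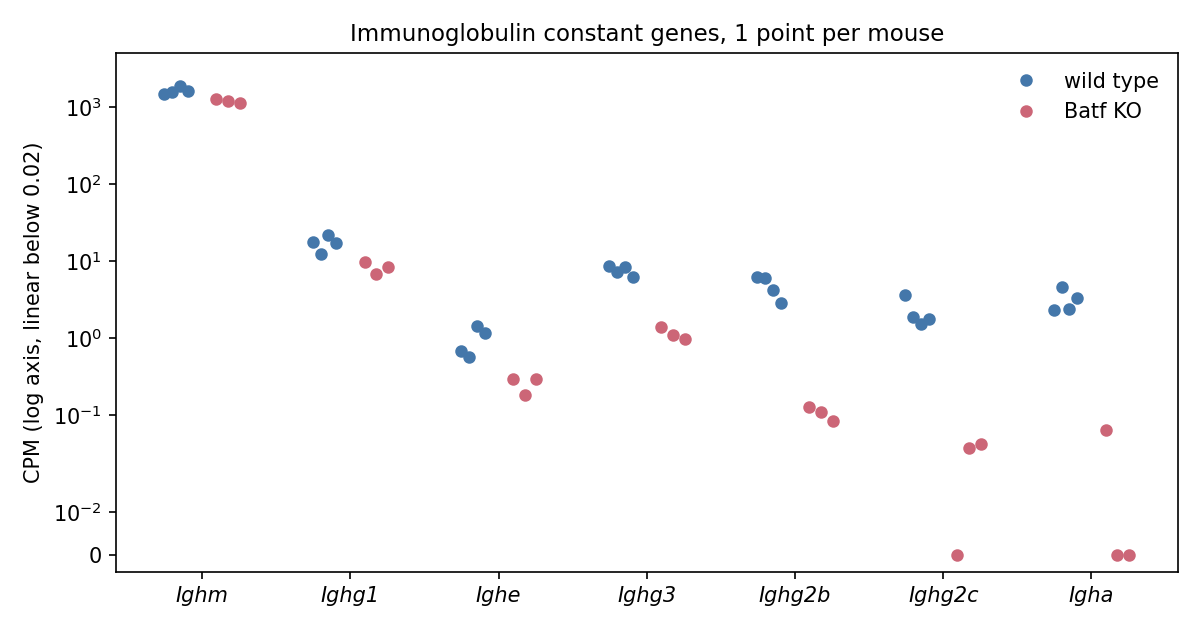
CPM of immunoglobulin constant genes per mouse, on an axis that is logarithmic above 0.02 CPM and linear below it (blue, 4 wild type; red, 3 Batf KO). Each gene is lower in Batf KO, and Ighg2c and Igha have 2 reads each over the 3 Batf KO libraries.

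Type I interferon response genes were higher in Batf KO: 10 of the 30 annotated members were listed, and all 10 were higher (Fisher's exact test, adjusted p = 0.0166). Members of a list can move together within a mouse, which this test does not take into account. Ifit3 rose 2.87-fold, the DNA sensor family gene Ifi204 rose 2.35-fold, Ifi44 2.27-fold and the RNA sensor gene Oas1a 1.83-fold. All 10 passed adjusted over the list alone, as they had to. Adjusted over 19734 genes in the edgeR test, 0 of 10 passed, although each passes in the authors' deposited table. The geometric mean over the 10 genes was 57.0 to 62.8 CPM in the Batf KO libraries and 17.0 to 45.3 CPM in the wild-type libraries, with the highest wild-type value in replicate 2. Cell cycle genes were also higher. Of the 32 annotated members, 7 were listed, and all 7 were higher (Fisher's exact test, adjusted p = 0.0457), among them Ccnd3 (1.65-fold), the topoisomerase gene Top2a (1.39-fold), E2f1 (1.40-fold) and E2f2 (1.80-fold). All 7 passed adjusted over the list alone, as they had to, and 0 of 7 adjusted over 19734 genes. The list's adjusted Fisher p was 0.0687 without Batf KO replicate 3 and 0.0639 with a mean CPM of at least 5.

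**Figure D3:**
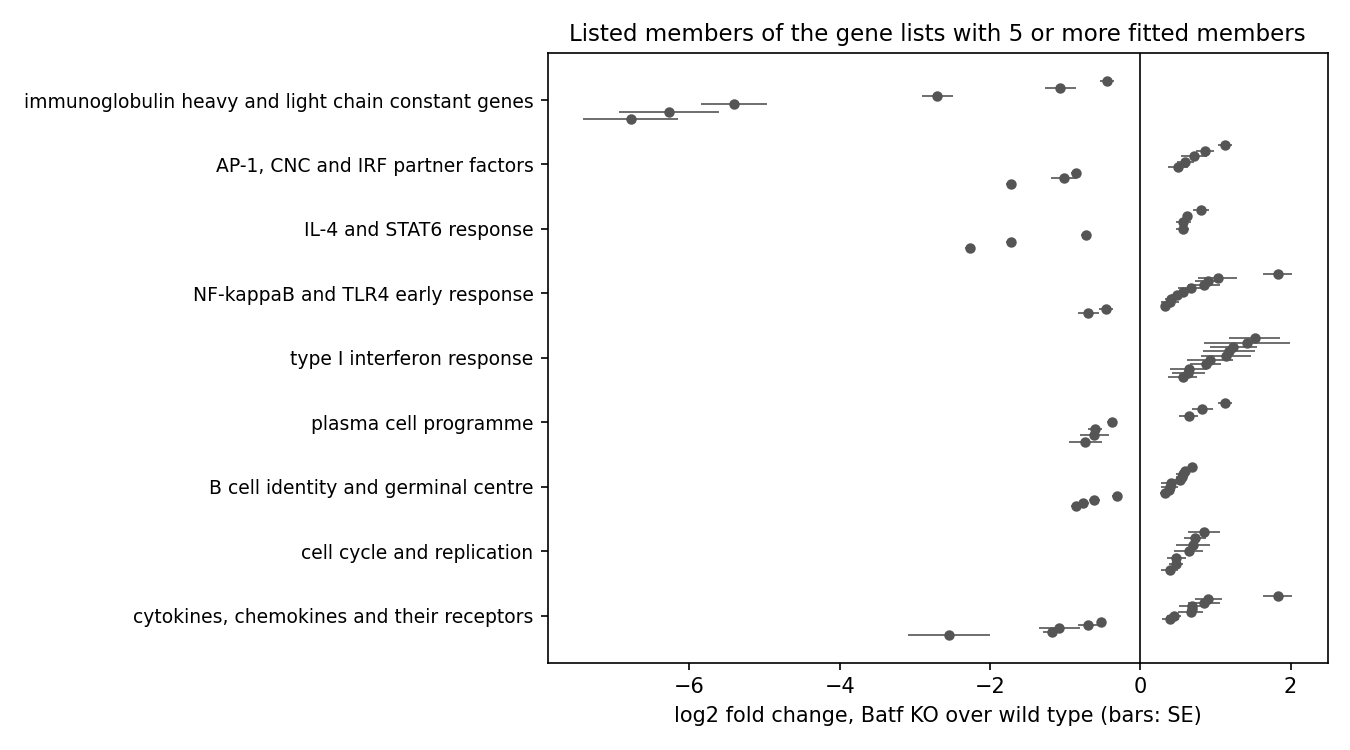
Log2 fold change of Batf KO over wild type for the fitted members of the 9 lists with at least 5 fitted members, 1 point per gene, with bars for the SE. The immunoglobulin points lie below 0 and the interferon and cell cycle points above 0, and the values of Igha and Ighg2c rest on 2 Batf KO reads each.

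Genes of the NF-kappaB and TLR4 early response had 10 higher and 2 lower members among 36, which did not pass the test after adjustment (Fisher's exact test, p = 0.0372, adjusted p = 0.0837). The costimulatory genes Cd86 and Cd40 rose 1.49-fold and 1.26-fold, Nfkbid rose 1.40-fold, and the lower members were Il6 and Mir155hg. All 12 passed adjusted over the list alone, as they had to, and 4 of 12 adjusted over 19734 genes. Immediate early genes of the handling stress list moved in the same direction, with 3 of 22 listed and all 3 higher (Ier2, Dusp1 and Zfp36), of which 1, Ier2, passed adjusted over 19734 genes. Among AP-1 and IRF partner factors, 5 fitted members of 23 were higher and 3 lower (adjusted p = 0.816, Fisher's exact test). Irf4 rose from 662 ± 68.8 CPM (SD, n = 4) to 1442 ± 108 CPM (SD, n = 3) and Jun rose 1.81-fold, whereas Bach2, a repressor of plasma cell differentiation, fell 1.81-fold. The IL-4 and STAT6 list was divided, with 4 of 26 higher and 3 lower (adjusted p = 1.0, Fisher's exact test). The IL-4 receptor gene Il4ra fell from 229 ± 10.8 CPM (SD, n = 4) to 138 ± 3.76 CPM (SD, n = 3), Gadd45b rose 1.54-fold, and the other lower members were Batf and Nfil3. Adjusted over 19734 genes, 6 of 8 fitted AP-1 and IRF genes and 7 of 7 IL-4 and STAT6 genes passed. All passed adjusted over the list alone, as they had to.

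The plasma cell list had 3 higher and 4 lower members of 22 (adjusted p = 0.816, Fisher's exact test), with Irf4 and Trib1 (1.77-fold) higher and the chaperone gene Dnajb9 (1.52-fold) and the stress sensor gene Atf6 (1.30-fold) lower. The B cell identity and germinal centre list had 9 higher and 4 lower fitted members of 31 (adjusted p = 0.473, Fisher's exact test). Ccr7, the receptor that guides lymphocytes to T cell zones, rose from 915 ± 28.1 CPM (SD, n = 4) to 1477 ± 69.5 CPM (SD, n = 3), and Ms4a1, which encodes CD20, rose 1.52-fold. The coactivator gene Pou2af1 fell 1.70-fold. Cytokine and receptor genes had 8 higher and 5 lower fitted members of 50 (adjusted p = 0.816, Fisher's exact test), with Il10 higher and Il16 (2.27-fold) and Il21r (1.43-fold) lower. Adjusted over 19734 genes, 4 of 7 plasma cell genes, 8 of 13 B cell identity genes and 4 of 13 cytokine genes passed. All passed adjusted over the list alone, as they had to.

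Lists with fewer fitted members were not tested. The Wnt list had 2 of 44 members listed, Wnt10a and Wnt10b (1.67-fold), both higher. Bhlhe40 fell 2.16-fold and Bhlhe41 was higher by 1.92-fold among 3 listed circadian and PAR bZIP genes of 19, the other being Nfil3. Of 26 apoptosis genes, Casp8 (1.57-fold) and Bcl2 (1.54-fold) were lower and Bcl2l1 (1.48-fold) was higher. Of 18 marginal zone and B1 genes, Zbtb32 was lower (2.22-fold), and Cd9 and Bhlhe41 were higher. Of 28 glycolysis and hypoxia genes, Egln3 rose 2.59-fold and Pfkp fell 1.34-fold. Of the genes in these lists, Bhlhe41, Bcl2, Zbtb32 and Cd9 did not pass the edgeR adjustment over 19734 genes. None of 31 MYC and ribosome biogenesis genes was listed.

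The authors listed 752 of 19734 genes, so a low number of listed markers is no evidence that other cells differ little. Few markers of other spleen cells were listed. They were Cd8b1 (higher) and Tbx21 (lower) among 29 T and NK genes, Zbtb46 (higher) among 35 myeloid genes and Pf4 (higher) among 17 erythroid and platelet genes. Tbx21, Zbtb46 (edgeR adjusted p = 0.0744) and, without the filter, Pf4 (edgeR adjusted p = 0.175) did not pass adjusted over 19734 genes. None of 18 stromal genes and none of the 7 sex-linked genes of that list was listed. Outside the lists, the Y chromosome gene Usp9y, chosen after its values were seen, has the largest increase in the authors' deposited table (log2 fold change 7.63, FDR 0.000202). All of its 72 reads were in Batf KO replicate 1, and the other 6 libraries had 0. Without that library, 329 fitted genes were higher and 326 lower. The sex of the mice is not given in the sources used here. Genes outside the table have no level here, so a small share of other cells was not measured.

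Among neighbours of Batf on chromosome 12, Flvcr2 (85746539 to 85813585) rose 3.11-fold. Jdp2 (85599027 to 85639878), an AP-1 family repressor gene, fell 2.03-fold, and Npc2 fell 1.41-fold. Npc2 did not pass the edgeR adjustment over 19734 genes (adjusted p = 0.104). The 5S ribosomal RNA gene n-R5s64 (85718477 to 85718595, minus strand) lies 9.39 kb beyond Batf. It had the largest increase of the fitted named genes, from 19 reads in the 4 wild-type libraries to 292 in the 3 Batf KO libraries. Its span overlaps the annotated microRNA gene Gm47285, and reads of the 2 cannot be separated here.

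**Figure D4:**
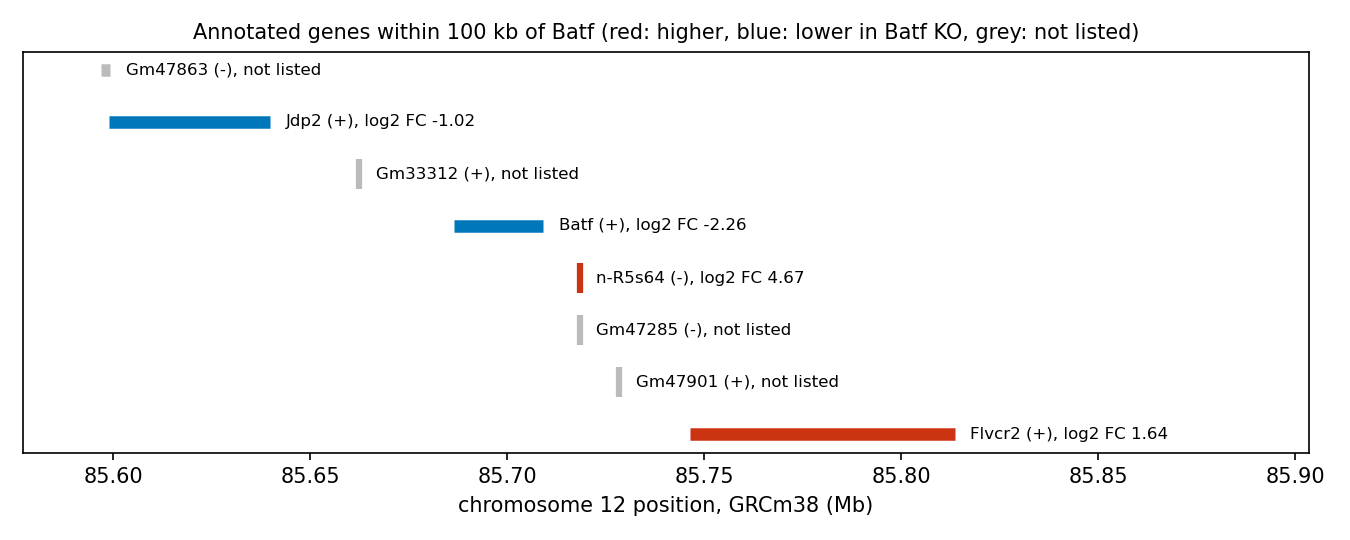
Annotated genes within 100 kb of Batf on chromosome 12 (GRCm38, position in Mb), with strand and log2 fold change of Batf KO over wild type (red, higher; blue, lower; grey, not in the table). Besides Batf, n-R5s64, Flvcr2 and Jdp2 are listed.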

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

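In groups of 4, a sample was singled out when its gap to the nearest other sample took a larger part of the group's range than Dixon's 95% critical value. This was applied to 68 sets of wild-type values, where chance gives about 3.4 such samples, and 2 were found. Cd86 was 217 CPM in wild-type replicate 3, and 255 to 260 CPM in the other 3. E2f2 was 22.3 CPM in wild-type replicate 2 and 14.6 to 15.2 CPM in the other 3. The groups of 3 Batf KO libraries were not tested. No explanation was tested for either value.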

How the results depend on the processing

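The adjustment over 19734 genes, with and without the filter, and DESeq2 were chosen after seeing the data. The limma test with a pseudocount of 0.5 CPM was the test first planned for CPM. Its use as an alternative was chosen after seeing the data. None of the 65 named gene results and none of the 2 counts or 9 list results reversed under the alternatives that gave them a value. The 2-fold minimum was applied to the 2 counts alone, and the authors' FDR to no list. Other genes, gene families, chromosome bins and the neighbourhood of Batf were not recomputed under each alternative, and the text gives those values that were. The counts of 339 higher and 328 lower genes became 134 and 152 when adjusted over 19734 genes, 139 and 171 when the filter was also dropped, and 61 and 73 with a 2-fold minimum. Each of these is stricter by construction. Under the other alternatives both counts stayed within 1.5 times the main value, and 630 genes were called whichever library was left out. Because the genes had been selected on the same libraries, this stability is not independent evidence, and neither is that of the named genes below. Batf, Nfil3 and Wnt10a passed under each alternative run. Mir155hg kept its log2 fold change of -0.46 and did not pass over 19734 genes (edgeR adjusted p = 0.0660, or 0.0630 without the filter). Of 65 named gene results, 20 did not pass over 19734 genes and 19 without the filter, and none lost its call when a library was left out. For the immunoglobulin constant list the adjusted Fisher p was 0.283 over 19734 genes and 0.302 without the filter, and 0.0454 to 0.0687 with a library left out, the higher values coming without Batf KO replicate 2 or 3. For the cell cycle list it was 0.0639 with a mean CPM of at least 5 and 0.938 over 19734 genes without the filter, and 0.0329 to 0.0687 with a library left out, the highest without Batf KO replicate 3. The cause of the changes in the lists was not tested. Over 19734 genes no interferon gene passed, so that list had no value there, and with the filter neither had the cell cycle list. The planned set tests with a preset or estimated correlation and the rotation test were not run, because the table is selected. No paired analysis was possible because the mouse numbers differ between the groups. Depth limits genes with few reads, such as Igha and Ighg2c with 2 reads each in Batf KO.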

Other observations

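Of the tests in this part, all but the scaling test of the interferon genes were chosen after the result was seen. Gene families with at least 5 listed members were compared with the other listed genes by Fisher's exact test, adjusted over 14 families. All 14 listed immunoglobulin heavy chain variable genes were lower in Batf KO, with a median log2 fold change of -0.94 (adjusted p = 0.000556). All 7 listed genes with Gimap symbols, which lie together on chromosome 6, were lower (adjusted p = 0.0356). They are 6 genes of lymphocyte GTPases and Gimap1os, a transcript on the opposite strand that overlaps Gimap1, whose reads cannot be told from it without strand. Gimap3 fell from 332 ± 29.3 CPM (SD, n = 4) to 181 ± 8.82 CPM (SD, n = 3). All 8 listed genes with Ifi symbols were higher (adjusted p = 0.0356). With Gimap1os left out, the 6 Gimap genes (adjusted p = 0.0628) and the Ifi genes (adjusted p = 0.0533) did not pass. Adjusted over 19734 genes in the edgeR test without the filter, 1 of 14 variable genes, all 6 Gimap GTPase genes and 0 of 8 Ifi genes passed. Many members of these families lie side by side and share sequence, so they are not independent. By share of protein-coding genes listed, the first of 366 bins of 5 Mb was chromosome 13 from 10 to 15 Mb, with 5 of 22 listed and all 5 higher. The bin of chromosome 13 that holds Irf4 ranked 4, with 7 of 46 listed and all 7 higher, among them Serpinb1a, Serpinb6b and Serpinb9. On chromosome 1, the 5 Mb with the Slam and Ifi genes had 13 of 113 protein-coding genes listed. A strain-derived chromosome segment was asked about as its source, and the bin ranked 8 of 366 by share of genes listed. A lower rank does not exclude such a segment, so this stays open.

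Genes beside Batf were changed. Within 100 kb, 3 of the 7 other annotated genes were listed, while the 95th percentile of 680 equal windows around other listed protein-coding genes was 2 and 10 windows (1.47%) held as many. This is consistent with a local effect of the targeted Batf allele, a hypothesis, but loss of BATF as a regulator of its neighbours was not tested and stays open. Carry-over of 5S ribosomal RNA in the Batf KO libraries would raise other 5S genes, and 0 of 179 other n-R5s genes were listed. Since genes outside the table have no value here, this explanation cannot be told apart for n-R5s64, while Flvcr2 and Jdp2 are protein-coding genes.

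Constant genes of switched isotypes were lower. Over 6 isotypes the highest upper bound of the Batf KO to wild-type ratio was 0.509, that of Ighg1. The 6 genes had been selected for a difference between the same libraries, and the intervals cover counting error only. These bounds therefore do not decide whether chance played a part. Loss of IL-4-driven induction as the whole cause was argued against, since 4 of 4 isotypes that IL-4 does not drive fell further than Ighg1 and Ighe. The counting intervals, which leave out the spread between mice, were apart for 3 of the 4, and that of Ighg3 overlapped that of Ighe. The median log2 fold change of these 4 minus that of Ighg1 and Ighe was -4.36, or -3.38 with Igha and Ighg2c at the upper bound of their ratio, which is consistent with fewer cells that had switched before culture, a hypothesis. A direct effect of genotype on these transcripts stays open, and so do unswitched germline transcripts, which LPS can induce from Ighg3 and Ighg2b and which gene counts do not separate from switched ones.

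Interferon response genes were higher. At least 7 of 10 members stayed past the threshold whichever mouse was left out. This count does not decide whether a single mouse was the source. The members were selected on the same libraries, and all 667 fitted genes pass that threshold with every mouse included. The median log2 fold change of the members ran from 0.82 (without wild-type replicate 4) to 1.32 (without wild-type replicate 2). The median thus stayed positive whichever mouse was left out, while its size moved with the mouse left out. Because all the mice together had selected these genes, the medians do not decide the question either. The median log2 fold change of the members was 0.99 with scaling set on the listed genes and 1.03 without. That scaling moved the median of all listed genes by only -0.04. It rests on genes selected for a difference, and genes outside the table have no value here. Scaling between libraries as the source was therefore not decided. Genes of the chromosome 1 Ifi cluster did not make up most of the members, since 2 of the 10 lie on chromosome 1. That number follows from which genes the list holds, so it does not test the cluster itself. Ifi207, Ifi209 and Ifi214 on chromosome 1 were also higher and are not members of the list. Position alone does not show what raised the members elsewhere. What stays open is how far wild-type mice differ by themselves: replicate 2 had a geometric mean of 45.3 CPM and replicate 4 had 17.0 CPM. Between genotypes 8 of 10 members did not overlap, against 641 of all 667 fitted genes. Since the genes were selected for such a difference, the 8 carry no evidence of their own.

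Over the 35 splits of the 7 libraries into 3 and 4, 1 split, the real one, gave as many genes higher (339), and likewise 1 for genes lower (328), and the highest other count in a direction was 95. That split set wild-type replicates 1, 3 and 4 against the rest. Because the genes were selected on the real split, these counts do not show whether chance can be excluded.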
